A study of Homo sapiens with 18 samples.

How the data were processed

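The series holds 18 chromatin immunoprecipitation sequencing (ChIP-seq) samples of A673, an established Ewing sarcoma cell line. Peak lists of 5 of them were analysed: RING1B (2 replicates), monoubiquitinated histone H2A (H2Aub1, 2 replicates) and EWSR1-FLI1 (1 sample). For the other 13 samples (inputs, BMI1, CBX7 and the RING1B knockdown with its control) no peak list was used here, so the effect of RING1B knockdown was not analysed here.

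The submitters' processing notes name Bowtie and hg19 for all samples, and also mm9 for the samples of the RING1B and H2Aub1 part of the series, without saying what mm9 was used for. The version of Bowtie is not given in the sources used here. Peak names in the deposited files begin with MACS, a peak caller whose version is not given in the sources used here. There is 1 deposited list per sample, and replicates were treated as called separately. The title lines of the files differ between lists, also between the replicates of RING1B and of H2Aub1, in names whose meaning is not given in the sources used here. Neither these lines nor the labels state for each list whether input served as background or which filters were applied. Each peak carries a score from the authors, whose scale is not given in the sources used here. The lowest score in each list lay close to 50. The score was used only to rank and describe peaks within a list, and score correlations were taken over paired peaks. RING1B scores of exactly 3100 were found for 4 peaks of replicate 1 and 1 peak of replicate 2, and H2Aub1 replicate 1 had 2 such peaks.

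The lists hold no read counts, so the sequencing depth of each sample is unknown, and a longer list can come from deeper sequencing. All coordinates are hg19 as deposited, written 1-based. Chromosome lengths of hg19 came from the GenomeInfoDb package of R, and 0 peaks lay beyond a chromosome end. Gene counts per chromosome came from a RefSeq table of GRCh38 and were used only as counts of protein-coding genes per chromosome, divided by hg19 lengths.

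Reproducible regions were made by merging peaks of both replicates that shared at least 1 bp and keeping merged regions with a peak of each replicate. This gave 1587 RING1B regions out of 4879 in the union and 6408 H2Aub1 regions out of 28121. A merged region spans all peaks joined in it and is at least as wide as the widest of them. EWSR1-FLI1 had 1 list, which was used as deposited.

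A region was called overlapped when it shared at least 1 bp with a region of the other list. Shares are given with 95% Wilson intervals, which cover counting error over regions only, and neighbouring regions are not independent. Each share was tested against 1000 placements of the same regions, kept at their width, at random positions on the same chromosome (one-sided permutation test, smallest possible p = 0.001). Assembly gaps were not left out of the placements, and open chromatin and mappability were not matched. An excess over random placement therefore cannot separate a specific relation from sites that are prone to peaks in any list. Association of EWSR1-FLI1 and H2Aub1 within RING1B regions was tested by Fisher's exact test (two-sided), and the 95% interval of the odds ratio came from leaving out each chromosome in turn (block jackknife). Medians and correlations were tested with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Benjamini-Hochberg adjustment was applied within each family of tests.

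The overlap tests, the association test, the alternatives for them and the rule for named regions were fixed before the data were examined. That rule took, for RING1B regions with EWSR1-FLI1 and for those with H2Aub1, the 10 regions with the highest score of the authors. Here the highest score of each reproducible region was ranked among all reproducible RING1B regions in each replicate, and both percentile ranks were averaged. Comparisons by score quartile, of region width and neighbouring regions, of the reverse H2Aub1 overlaps, of score correlations and along chromosomes were not part of that plan and were added later. The alternatives asked for an overlap of at least 50% of the shorter region, or a region centre within 500 bp of the other region. Others used the 50% of each list with the highest scores, the union of replicates, autosomes only, the longer list as denominator, each replicate left out in turn, and a background in which each region was moved by 50 kb to 500 kb. A further alternative paired RING1B and H2Aub1 replicates by number.

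A genome and a gene annotation of hg19 were not used here. Regions are therefore given by coordinates without gene names, and the planned share near promoters, the share with GGAA repeats and the tests of 9 gene lists (438 genes) were not run.

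The overlap test was tested on simulated data for the EWSR1-FLI1 list of 2145 peaks against a list of the size of RING1B replicate 1. Planned shares of 40% and 5% were recovered within 0.233 and 0.280 percentage points in 10 draws each, and 10 of 10 draws passed the threshold at either share. With no planned sharing, 0 of 10 draws passed. For simulated sets of 1600 regions with an odds ratio of 0.25, the median estimate was 0.246, and 94 of 100 intervals held the planned value. Simulated regions were not clustered, so neither check covers the dependence between neighbouring regions in the lists. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.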

Results

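Ewing sarcoma cells of the A673 line carry EWSR1-FLI1, a fusion of EWSR1 with the DNA-binding ETS factor FLI1. RING1B is a ubiquitin ligase of Polycomb repressive complex 1 and deposits the H2Aub1 mark on histone H2A. ChIP-seq peaks were compared for EWSR1-FLI1 (1 sample, without replicate), RING1B (2 replicates) and H2Aub1 (2 replicates). The EWSR1-FLI1 list held 2145 peaks covering 2.21 Mb, with a median width of 985 bp. RING1B gave 2573 peaks (3.15 Mb) in replicate 1 and 3945 peaks (4.67 Mb) in replicate 2, with median widths of 1029 and 1035 bp. H2Aub1 gave far longer lists, with 26423 peaks (39.7 Mb) in replicate 1 and 10268 peaks (14.6 Mb) in replicate 2, and its widest peak spanned 29707 bp. The labels do not say that replicates came from separate cultures, so agreement between them may be technical.

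Most peaks of the shorter RING1B and H2Aub1 lists were found again in the other replicate, most completely at the highest scores, whereas most peaks of the longer lists were not. Of the 2573 RING1B peaks of replicate 1, 1611 overlapped a peak of replicate 2 (62.6%, Wilson interval 60.7 to 64.5%), and 7942 of the 10268 H2Aub1 peaks of replicate 2 overlapped replicate 1 (77.3%, 76.5 to 78.1%). In the top score quartile 96.4% of RING1B replicate 1 peaks were found again, against 36.9% in the bottom quartile. For H2Aub1 replicate 2 these shares were 98.5% and 55.6%. Scores of both replicates were correlated over the 1587 reproducible RING1B regions (Pearson r = 0.878, Spearman rho = 0.632) and over the 6408 reproducible H2Aub1 regions (r = 0.756, rho = 0.610), with regions not being independent replicates. Without the 2 regions farthest from the median, r was 0.865 and 0.749. Each p was 1e-05, the smallest 100000 permutations can give (adjusted p = 1.5e-05 over 6 relations). Random placement gave mean overlaps of 0.333% for RING1B and 2.72% for H2Aub1 (permutation p = 0.001 for both, the smallest possible, adjusted p = 0.001 over 8 overlaps). With regions moved by 50 kb to 500 kb instead, the mean overlaps were 0.571% and 10.8%. As a share of the longer lists the overlaps were 40.9% for RING1B replicate 2 and 26.6% for H2Aub1 replicate 1.

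The title of the series concerns recruitment of EWSR1-FLI1 by RING1B, for which shared occupancy is the comparison these lists allow. EWSR1-FLI1 and RING1B occupied many of the same sites in A673 cells. A reproducible RING1B region was present at 897 of the 2145 EWSR1-FLI1 peaks (41.8%, 39.7 to 43.9%), and 892 of the 1587 RING1B regions carried EWSR1-FLI1 (56.2%, 53.8 to 58.6%). Random placement gave 0.148% and 0.197%, so the observed shares were 282 and 285 times higher (permutation p = 0.001, the smallest possible, for both). Placements were not matched for open chromatin, so the size of the excess does not show how specific the sharing is. Against regions moved by 50 kb to 500 kb, the excess was 148-fold and 149-fold, and without RING1B replicate 1 it was 179-fold and 183-fold against random placement (177-fold and 178-fold for the union). It was higher, at 525-fold and 513-fold, for the highest-scoring 50% of each list, and 447-fold and 460-fold under the 50% overlap rule. The 10 EWSR1-FLI1 peaks with the highest scores all overlapped RING1B, as did 99 of the top 100 (94.6 to 99.8%). The share of EWSR1-FLI1 peaks with RING1B depended on how replicates were combined, with 67.6% for the union of both. The share of RING1B regions with EWSR1-FLI1 was 29.7% for the union and 29.7% without RING1B replicate 1.

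Co-occupancy fell steeply with the EWSR1-FLI1 score. From the top to the bottom score quartile, 80.6%, 46.3%, 25.6% and 14.7% of EWSR1-FLI1 peaks overlapped RING1B (433 of 537 at the top and 79 of 536 at the bottom, Fisher's exact p = 3.09e-112, adjusted p = 7.41e-112 over 12 quartile comparisons). The median EWSR1-FLI1 score was 166 at the 897 peaks with RING1B and 74.1 at the 1248 peaks without (permutation p = 1e-05, the smallest possible). Of these 1248 peaks, 554 (44.4%) overlapped a RING1B peak found in a single replicate, and 694 peaks, 32.4% of the EWSR1-FLI1 list, had no RING1B peak in either replicate. With a single RING1B list the bottom quartile held 27.6% (replicate 1) or 31.5% (replicate 2), and the top quartile 87.9% or 86.2%. For the union of both RING1B lists these shares were 44.8% at the bottom and 93.5% at the top.

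**Figure D1:**
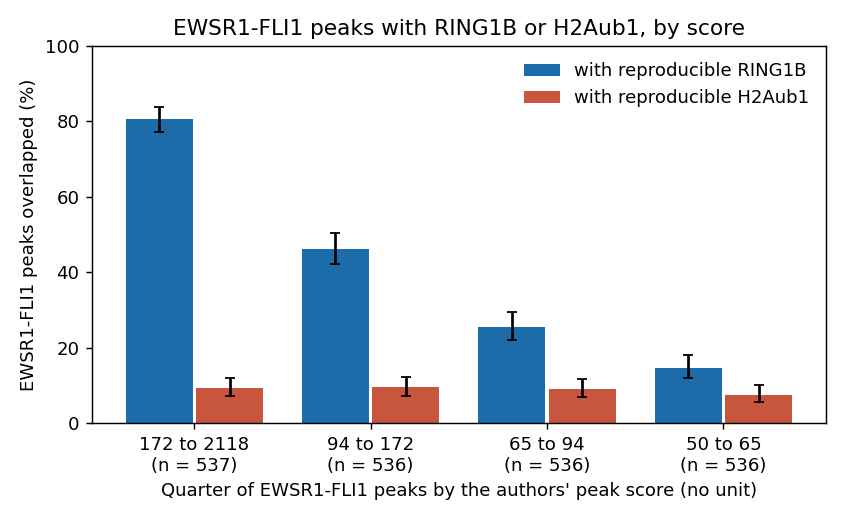
Percentage of EWSR1-FLI1 peaks that overlapped a reproducible RING1B region (blue) or H2Aub1 region (red) in each score quartile, with the authors' score range on the x axis and 95% Wilson intervals as error bars. RING1B overlap fell from 80.6% to 14.7%, while H2Aub1 overlap lay between 7.46% and 9.51%.

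At shared sites the peaks of both proteins were nearly concentric. The median distance between peak centres was 63 bp for the 1169 EWSR1-FLI1 peaks overlapping RING1B replicate 1 and 66 bp for the 1174 overlapping replicate 2. Over the 892 shared regions the EWSR1-FLI1 score rose with the RING1B score in replicate 1 (r = 0.747, rho = 0.668) and in replicate 2 (r = 0.755, rho = 0.615). These correlations are across regions, each with permutation p = 1e-05, the smallest possible (adjusted p = 1.5e-05). Without the 2 farthest regions r was 0.746 and 0.752.

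The RING1B region with EWSR1-FLI1 that ranked highest lay on chromosome 8 from 56305006 to 56307694 (hg19), with RING1B scores of 2082.32 and 1416.76, and held the highest-scoring EWSR1-FLI1 peak of the list (2117.51). It was followed by regions on chromosome 14 (97681312 to 97685033, EWSR1-FLI1 score 1547.05), chromosome 8 (12784203 to 12786235, 789.7), chromosome 2 (177520162 to 177522444, 1485.05) and chromosome 6 (131703722 to 131706297, 1341.85). The remaining regions of the top 10 lay on chromosome 18 (10461586 to 10463446), chromosome 7 (116107824 to 116109571 and 91495363 to 91496926), chromosome 14 (97531782 to 97533638) and chromosome 1 (58169623 to 58171283). None of these 10 regions overlapped a reproducible H2Aub1 region.

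H2Aub1 was present at a minority of RING1B sites, and most H2Aub1 regions had no RING1B peak. H2Aub1 was present at 315 of the 1587 RING1B regions (19.8%, 18.0 to 21.9%), 21.5 times the random mean of 0.923%. For the union of replicates 21.6% of RING1B regions had H2Aub1, beside the 29.7% with EWSR1-FLI1, and the difference between these shares was not tested. Conversely 319 of the 6408 H2Aub1 regions held RING1B (4.98%, 4.47 to 5.54%), 20.9 times the random mean. Without H2Aub1 replicate 2 these excesses were 11.8-fold and 12.4-fold, and for the union 9.26-fold and 9.57-fold. Each had permutation p = 0.001, the smallest possible. Scores of the mark and the enzyme were weakly related where they met, with r = 0.123 and rho = 0.159 over 313 regions in replicate 1 (permutation p = 0.0279 and 0.00527, adjusted p = 0.0334 and 0.00632) and r = 0.0918 and rho = 0.141 over 273 regions in replicate 2 (permutation p = 0.125 and 0.0198, adjusted p = 0.125 and 0.0198). Without the 2 farthest regions r was 0.141 and 0.116. The share of H2Aub1 regions with RING1B was 8.36% without RING1B replicate 1 and 1.92% without H2Aub1 replicate 2, and it was 2.497% when a region centre had to lie within 500 bp and 3.03% when 50% of the shorter region had to be shared.

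Within RING1B regions, EWSR1-FLI1 and H2Aub1 tended to mark different sites. H2Aub1 was found at 81 of 892 RING1B regions with EWSR1-FLI1 (9.08%, 7.37 to 11.1%) and at 234 of 695 without it (33.7%, 30.3 to 37.3%). The odds ratio was 0.197 (95% interval 0.137 to 0.283 over 23 chromosomes, Fisher's exact p = 1.71e-34). Reproducible RING1B regions thus divided into 811 with EWSR1-FLI1 alone (51.1%), 234 with H2Aub1 alone (14.7%), 81 with both (5.10%) and 461 with neither (29.0%). The odds ratio stayed below 1 in 9 alternatives but ranged from 0.0599 for the highest-scoring 50% of each list to 0.577 for the union, and it was 0.0781 under the 50% overlap rule. Without RING1B replicate 1 it was 0.571 (0.422 to 0.773), and regions with neither feature then formed the largest class (2330 of 3945, with 1056 carrying EWSR1-FLI1 alone), as they did for the union (2602 of 4879).

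RING1B regions with H2Aub1 alone were broader than those with EWSR1-FLI1 alone and more often had another RING1B region nearby. Their median width was 1915 bp against 1272 bp (permutation p = 1e-05, the smallest possible, adjusted p = 2e-05 over 6 comparisons), and 63 of 234 (26.9%) exceeded 3 kb against 8 of 811 (0.986%). The 81 regions with both features, which also carried the mark, had a median of 1157 bp, and 0 of them exceeded 3 kb. Another RING1B region, of any class, lay within 50 kb of 48.7% (42.4 to 55.1%) of the regions with H2Aub1 alone and of 23.4% (20.6 to 26.5%) of those with EWSR1-FLI1 alone (odds ratio 3.11, Fisher's exact p = 4.93e-13). This odds ratio was 1.82 for the union. Of the regions with both features, 21.0% had another RING1B region within 50 kb. No minimum gap was required, and some neighbours were nearly adjacent. Examples start at 1275344 (4856 bp) and 1280213 on chromosome 7 and, for EWSR1-FLI1 alone, at 14560870 (1099 bp) and 14562027 on chromosome 4. Neighbours can thus be parts of the same broad region, and Fisher's test treats them as independent. Median RING1B scores were 210 against 154 in replicate 1 (permutation p = 0.00081, adjusted p = 0.00122) and 174 against 143 in replicate 2 (permutation p = 0.0055, adjusted p = 0.0055). Regions with neither feature had lower scores, with medians of 80.7 and 90.0 (permutation p = 1e-05 against EWSR1-FLI1 alone, adjusted p = 2e-05). RING1B regions with EWSR1-FLI1 alone lay a median of 449 kb from the nearest H2Aub1 region, and those with neither 313 kb (permutation p = 0.00321, adjusted p = 0.00385). The width ratio of 1.51 was 0.995 for the union (permutation p = 0.759), 1.02 without RING1B replicate 1 (permutation p = 0.357) and 1.22 without RING1B replicate 2 (permutation p = 1e-05, the smallest possible).

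**Figure D2:**
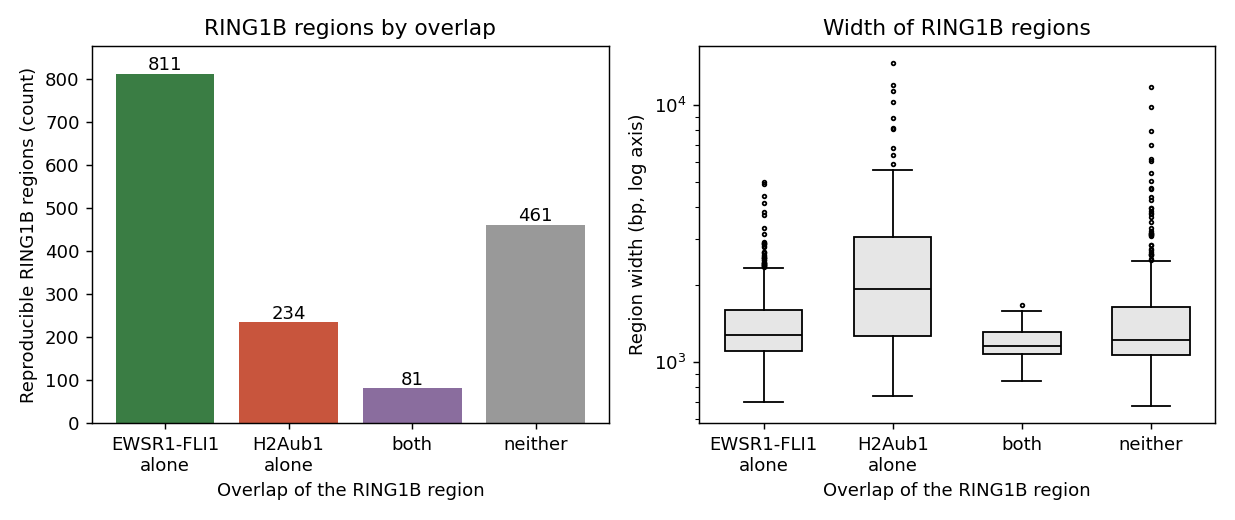
Left, number of reproducible RING1B regions by overlap with EWSR1-FLI1 and H2Aub1. Right, width of the regions in bp on a log axis, where boxes span the quartiles, lines mark medians (1915 bp for H2Aub1 alone and 1272 bp for EWSR1-FLI1 alone), whiskers reach the last value within 1.5 box lengths and circles are regions beyond.

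The RING1B region with H2Aub1 that ranked highest lay on chromosome 11 from 32455248 to 32466568 (11321 bp), with RING1B scores of 3100 and 3137.47 and H2Aub1 scores of 479.09 and 346.97. It lay in a stretch of chromosome 11 whose bounds were set by the widest RING1B regions (26586188 to 43667084). EWSR1-FLI1 and H2Aub1 peaks were also wider there than elsewhere, for a reason that was not tested. It was followed by regions on chromosome 7 (25899461 to 25908325, RING1B scores 3100 and 3100), chromosome 18 (19745201 to 19748616, 3100 and 2615.6), chromosome 14 (74706640 to 74710364, 2826.34 and 2217.45) and chromosome 15 (99162598 to 99168185, 3050.99 and 1444.49). The remaining regions of the top 10 lay on chromosome 2 (175201702 to 175206499), chromosome 7 (1275344 to 1280199 and 120969483 to 120976310), chromosome 1 (47695438 to 47697924) and chromosome 6 (134210928 to 134215571). None of these 10 regions overlapped an EWSR1-FLI1 peak.

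**Figure D3:**
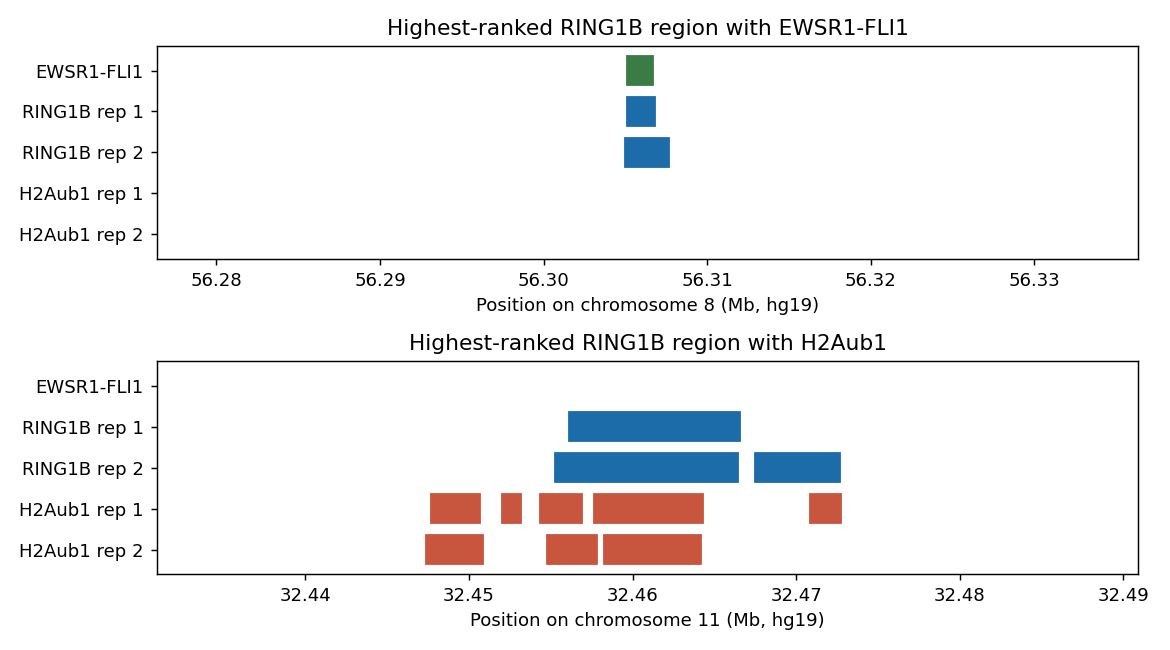
Peaks of the 5 lists around the highest-ranked RING1B region with EWSR1-FLI1 (top, chromosome 8) and with H2Aub1 (bottom, chromosome 11), with hg19 position in Mb on the x axis and a box per deposited peak. The chromosome 8 site holds EWSR1-FLI1 and RING1B peaks within a region of 2689 bp without H2Aub1, and the chromosome 11 site holds a RING1B region of 11321 bp with several H2Aub1 peaks and no EWSR1-FLI1.

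EWSR1-FLI1 peaks rarely carried H2Aub1, whether or not a reproducible RING1B region was present. The mark was found at 189 of 2145 EWSR1-FLI1 peaks (8.81%, 7.68 to 10.1%), 10.8 times the random mean of 0.812% (permutation p = 0.001, the smallest possible). Among peaks with a reproducible RING1B region 78 of 897 (8.70%) had H2Aub1, and among those without 111 of 1248 (8.89%). Of these 1248 peaks, 554 (44.4%) overlapped a RING1B peak of a single replicate, so this does not contrast bound with unbound peaks. The difference of -0.199 percentage points had an interval of -2.59 to 2.30 (Newcombe), and no difference was detected (Fisher's exact p = 0.938). H2Aub1 overlap did not differ detectably between the top and bottom score quartiles either (9.31% and 7.46%, Fisher's exact p = 0.322, adjusted p = 0.322), and 3 of the 100 EWSR1-FLI1 peaks with the highest scores had it. The share was 3.73% (5.98-fold) when 50% of the shorter region had to be shared, 15.1% (7.03-fold) for the union and 14.6% without H2Aub1 replicate 2.

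The mark and both proteins were also distributed differently along chromosomes. The outer 10 Mb at either chromosome end make up 15.15% of the hg19 length and held 37.9% of the reproducible H2Aub1 regions (36.7 to 39.1%), against 12.2% of the reproducible RING1B regions (10.6 to 13.9%) and 13.0% of the EWSR1-FLI1 peaks (11.6 to 14.4%). Assembly gaps were counted in this length, so 15.15% is only a rough expectation for where peaks can lie. The H2Aub1 share was 34.7% in replicate 1 and 37.8% in replicate 2, and the RING1B share was 12.4% (11.1 to 13.7%) in replicate 1 and 16.2% (15.1 to 17.4%) in replicate 2. The 5 Mb window with the most H2Aub1 regions lay on chromosome 8 (140000001 to 145000000) and held 140 of them beside 3 RING1B regions. It was followed by windows on chromosome 17 (75000001 to 80000000, 121 H2Aub1 and 2 RING1B regions) and chromosome 16 (85000001 to 90000000, 108 and 2). RING1B regions were densest on chromosome 2 (175000001 to 180000000) and chromosome 7 (90000001 to 95000000), with 15 RING1B regions each beside 13 and 3 H2Aub1 regions and 8 and 13 EWSR1-FLI1 peaks. Windows were singled out after their values were seen, and no test was run on them.

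**Figure D4:**
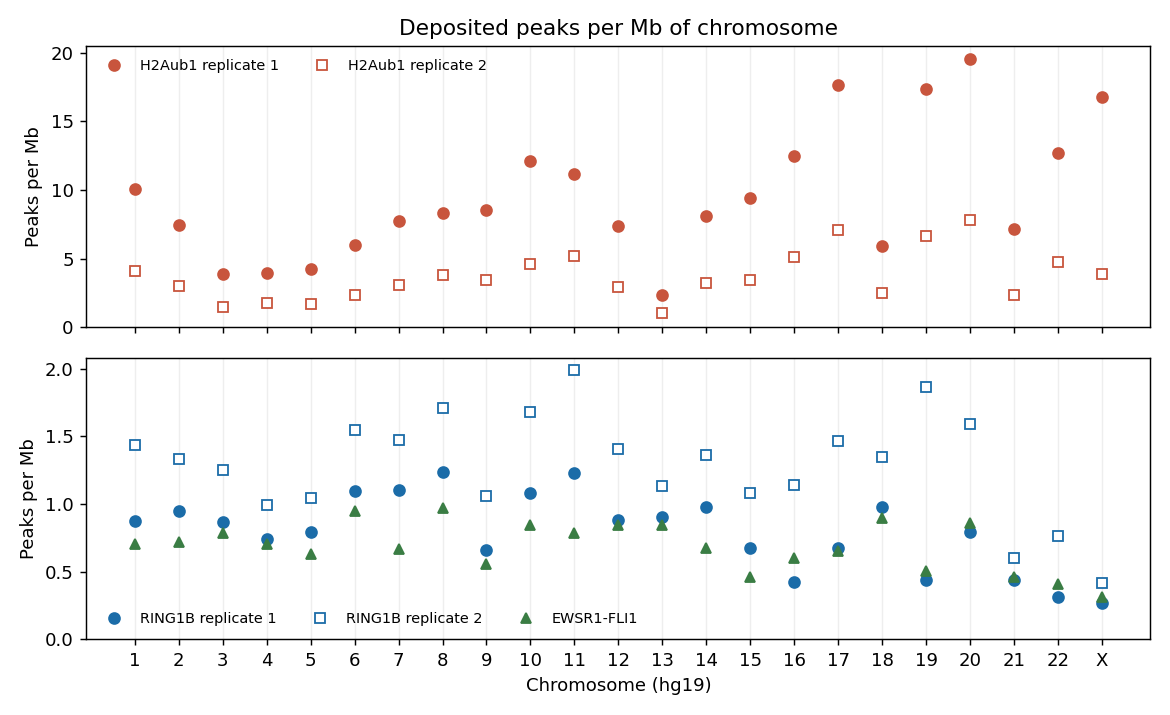
Deposited peaks per Mb of each chromosome (hg19 length) for H2Aub1 (top) and for RING1B and EWSR1-FLI1 (bottom), where filled circles are replicate 1, open squares replicate 2 and triangles the EWSR1-FLI1 list. On chromosome X, H2Aub1 replicate 1 reached 16.8 peaks per Mb and replicate 2 reached 3.92, while RING1B replicate 1 had 0.264 and EWSR1-FLI1 0.316. Chromosomes 17, 19 and 20 were higher than X in H2Aub1 replicate 1 (17.7, 17.4 and 19.6).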

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

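The comparison of chromosome X with autosomes, the same comparison for each chromosome and the reading of extra X copies were chosen after the result was seen, while the test of the longer list was written before it. Chromosome X drew attention because its share of the regions was higher for H2Aub1 than for RING1B, an enzyme of the mark. Among reproducible regions the odds of lying on X were 4.19 times higher for H2Aub1 than for RING1B (341 of 6408 against 21 of 1587, Fisher's exact p = 1.42e-14, Bonferroni-adjusted over 23 chromosomes p = 3.26e-13). The odds ratio was 6.77 in replicate 1 (Fisher's exact p = 6.40e-62, adjusted p = 1.47e-60) and 3.76 in replicate 2 (Fisher's exact p = 4.86e-32, adjusted p = 1.12e-30). X was not alone, although its odds ratio ranked highest of 23 chromosomes in all of these comparisons. Chromosome 22 followed with 3.96 for reproducible regions, 4.04 in replicate 1 and 2.46 in replicate 2, and chromosome 19 had 3.33, 3.96 and 1.39 (adjusted p = 0.0538 for the last, by Fisher's exact test). Peaks per Mb on X relative to autosomes were 2.03 and 1.17 for the H2Aub1 replicates, 0.301 and 0.311 for the RING1B replicates and 0.434 for EWSR1-FLI1. The odds ratios thus reflect a low density of RING1B on X more than a high density of H2Aub1. X makes up 5.11% of the hg19 length without Y, close to its share of the reproducible H2Aub1 regions. Per 5 Mb window of X, counts of H2Aub1 peaks ranged from 0 (as in 140000001 to 145000000) to 356 in replicate 1 (105000001 to 110000000) and 159 in replicate 2 (150000001 to 155000000).

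A candidate technical explanation for the excess in replicate 1 is its longer list, since its X share was 9.88% (9.52 to 10.2%) against 5.92% (5.48 to 6.39%) in replicate 2. Among its 10268 highest-scoring peaks, as many as replicate 2 holds, the X share was 7.29% (6.81 to 7.81%), still above replicate 2, which argues against list length as the whole cause, and a batch difference between these replicates, whose lists carry different names of unstated meaning, stays open as untested. Peaks on X tended to be weak, making up 11.8% of the bottom and 6.31% of the top score quartile in replicate 1, and 8.14% and 3.04% in replicate 2. In the top quartile the H2Aub1 density ratio of X to autosomes was 1.25 in replicate 1 and 0.581 in replicate 2. An excess over autosomes in both replicates was thus not seen among the strongest peaks. RING1B ratios in the top quartile were lower still, at 0.352 and 0.306, so H2Aub1 stayed higher on X relative to RING1B. Extra copies of X cannot be told apart from a higher level of the mark, because the EWSR1-FLI1 ratio of 0.434 lies below 1 but a low density of its binding sites on X could hide a gain, and no biological explanation was tested.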

How the results depend on the processing

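The reverse H2Aub1 overlaps, score quartile, width and neighbour results were added to the alternatives after the data were seen. Over 12 tested results, 92 alternatives kept direction and side of the threshold and 2 lost the threshold, 1 of them with a ratio just under 1. Of the 92, 70 stood at the smallest p the permutations can give, so their side of the threshold says little about the size of the overlap. Both exceptions concern the width of RING1B regions with H2Aub1 alone over EWSR1-FLI1 alone: the ratio of 1.51 became 0.995 for the union of replicates and 1.02 without RING1B replicate 1 (1.22 without RING1B replicate 2), and the cause was not tested. With each replicate left out in turn, EWSR1-FLI1 peaks with RING1B ranged from 54.5 to 54.7%, RING1B regions with EWSR1-FLI1 from 29.7 to 45.4%, RING1B regions with H2Aub1 from 14.2 to 27.2%, EWSR1-FLI1 peaks with H2Aub1 from 7.37 to 14.6%, H2Aub1 regions with EWSR1-FLI1 from 1.51 to 1.87% (3.57% for reproducible regions, 0.968% by centres and 1.25% under the 50% rule) and the odds ratio within RING1B regions from 0.20005 to 0.571. Moving regions by 50 kb to 500 kb lowered the excess of the H2Aub1 replicate overlap from 28.4-fold to 7.17-fold and that of RING1B replicates from 188-fold to 110-fold. RING1B and H2Aub1 samples share only a number, and the replicate block gave 18.3% of RING1B peaks with H2Aub1 (24.1% and 12.6%), against 14.8% and 21.3% for crossed numbers, higher wherever the longer H2Aub1 list was used. Promoter, GGAA repeat and gene list analyses were not run for lack of an hg19 genome and annotation. Peak lists without read counts leave open whether a peak missing from the shorter list reflects depth.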

Other observations

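Tests of peak widths on chromosome 11, of wide H2Aub1 regions, of gene density and of the union of H2Aub1 lists were chosen after the results were seen, while what the stratified odds ratio and the correlation of EWSR1-FLI1 and RING1B scores would show was written down before these values were computed. Many of the broadest RING1B regions lay on chromosome 11, in a stretch where the peaks of all 5 lists were wide. Of the 10 widest reproducible RING1B regions, 7 lay there between 26586188 and 43667084, the widest from 31841786 to 31856330 (14545 bp). On this chromosome lay 17 of 99 regions wider than 3 kb (17.2%) against 89 of 1488 narrower ones (5.98%). This contrast was tested, but its p-value is not counted as support, because the widest regions had drawn attention to the chromosome. In this stretch the median peak width was 2.37 and 2.88 times that elsewhere for RING1B replicates 1 and 2, which served to find it, but also 2.08 times for EWSR1-FLI1 (17 peaks, 2048 against 984 bp) and 1.33 and 1.34 times for H2Aub1 (159 and 72 peaks). RING1B was not tested, since its widest regions set the bounds. Permutation p was 1e-05, the smallest possible, for EWSR1-FLI1 and H2Aub1 replicate 1 and 2e-05 for H2Aub1 replicate 2 (adjusted p = 1.5e-05 and 2e-05 over 3 lists). RING1B regions with EWSR1-FLI1 alone were wider there as well, with a median of 2394 bp over 10 regions against 1268 bp over 801 elsewhere, and 4 of the 8 wider than 3 kb were on chromosome 11. Without the stretch the width ratio of regions with H2Aub1 alone over EWSR1-FLI1 alone was 1.49. Genome-wide, H2Aub1 was present at 7 of the 10 and 32 of the 50 widest RING1B regions, and EWSR1-FLI1 at 0 and 4. From the side of the mark, H2Aub1 regions wider than 5 kb held RING1B in 133 of 770 cases (17.3%, 14.8 to 20.1%), 31.5 times the random mean, and narrower ones in 186 of 5638 (3.30%, 2.86 to 3.80%), 16.8 times the random mean (permutation p = 0.001 for both, the smallest possible). The 28 RING1B regions wider than 3 kb without EWSR1-FLI1 or H2Aub1 included 1 of 11712 bp on chromosome 11 (26586188 to 26597899), with RING1B scores of 208.88 and 81.15.

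The hypothesis that peaks follow the density of protein-coding genes was tested over 23 chromosomes, with 5 lists in the family. H2Aub1 peaks per Mb rose with gene density in replicate 1 (r = 0.657, rho = 0.750, permutation p = 0.00033 and 6e-05, adjusted p = 0.000825 and 0.00015) and in replicate 2 (r = 0.706, rho = 0.766, permutation p = 0.00014 and 3e-05, adjusted p = 0.0007 and 0.00015). Without the 2 farthest chromosomes r was 0.627 and 0.739. For EWSR1-FLI1 the relation was not detected and its sign was negative (r = -0.258, rho = -0.264, permutation p = 0.245 and 0.222, adjusted p = 0.245 and 0.277, r = -0.138 without the 2 farthest). RING1B replicates differed in sign (rho = -0.225 and 0.408, adjusted p = 0.302 and 0.0890, r = -0.332 and 0.412, adjusted p = 0.154 and 0.0933), and without the 2 farthest chromosomes r was -0.154 and 0.256.

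A hypothesis drawn from the report is that RING1B sites held by EWSR1-FLI1 are a class apart from RING1B sites with the H2Aub1 mark. Differences in RING1B width and score between the classes are argued against as the cause, since the odds ratio over 15 strata of width and score was 0.219 (0.163 to 0.293) beside 0.197 without strata. Marks missed by the shorter H2Aub1 list are argued against as well, because with the union of both H2Aub1 lists 14.7% of RING1B regions with EWSR1-FLI1 and 44.5% of those without had the mark, an odds ratio of 0.215 (0.152 to 0.304). The separation was weaker without RING1B replicate 1 (0.571), so its size depends on which RING1B peaks are counted. It was also measured only over regions chosen for RING1B, and what that choice contributes was not tested. EWSR1-FLI1 peaks as a whole had an H2Aub1 overlap 10.8 times the random mean (5.98 times under the 50% overlap rule). Placements were not matched for open chromatin, so this excess cannot show whether these peaks avoid the mark relative to comparable sites. The H2Aub1 share of EWSR1-FLI1 peaks was 8.70% with a reproducible RING1B region and 8.89% without it. The latter group includes peaks with RING1B in a single replicate. What sets the classes apart may lie in sequence or distance to genes, which was not tested.

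A further hypothesis is that part of the EWSR1-FLI1 peaks without RING1B were missed in the RING1B lists because RING1B signal falls with EWSR1-FLI1 signal. The correlation it needs was present, with rho = 0.615 (0.571 to 0.656) in the lower of both replicates over 892 shared regions. It is in line with the 44.4% of these peaks that had RING1B in a single replicate. Sites bound by EWSR1-FLI1 without RING1B stay open as well, because shared regions cannot show how RING1B behaves below its detection limit.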
